A study of Danio rerio with 18 samples.

How the data were processed

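Each of the 18 libraries came with a transcript quantification from Salmon, and the series came with 1 gene table covering all 18. Per the file headers, the transcript files hold TPM and estimated counts for 52340 entries, of which 50160 carry Ensembl transcript identifiers, 2176 are assembled by the submitters and 4 are control-like sequences with other names. TPM values deposited by the authors were not used here. The deposited estimated counts were rounded to whole numbers before the count models were fitted. The gene table deposited by the authors covers 27015 genes, 25935 with Ensembl identifiers and 1080 assembled loci, and its signal is treated as counts divided by 1 factor per library. Between 45.8% and 49.7% of its values above 0 in a library were whole multiples of 1 unit (tolerance 0.001 reads), and 13695 genes were whole in all 18 libraries, so whole reads could not be recovered for the table as a whole.

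Per the submitters' processing notes, the reads were processed with bcl2fastq 2.16.10, STAR 2.4.2a, cutadapt 1.9.1, GSNAP, Cufflinks 2.2.1, Salmon 0.6.0 and DESeq2 on genome build GRCz10. The notes used here do not give the role or the order of each tool. Ribosomal RNA was depleted and the libraries were stranded, per the labels.

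The main test was limma with a mean-variance trend on log2 of the normalized count plus 1, for genes with at least 10 normalized counts in at least 2 libraries of a fit, with Benjamini-Hochberg adjustment and a threshold of adjusted p 0.05. The plan made before the data were examined had named edgeR on estimated counts summed to genes as the main test. The sources used here hold no map from transcripts to genes, so that sum could not be made. edgeR was therefore run on single transcripts as an alternative, and limma on the gene table, planned as an alternative for the first 3 comparisons, became the main test. The choice was made before any test was run. The edgeR counts for transcripts stand beside the main counts in the report. A further 12870 genes with at least 18 reads were joined to 1 transcript each by matching values across the libraries, and edgeR and limma were repeated on these joined genes.

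There were 5 comparisons. Comparison A set the polysome-bound against the polysome-unbound fraction with stage as a block (12 libraries, 5 residual degrees of freedom). Comparison B set the unfractionated libraries of 3.5 and 5.3 hpf against the 4 earlier ones (6 libraries, 4 residual degrees of freedom). Comparison C tested whether the bound over unbound ratio differed between the 2 late and the 4 early stages (12 libraries, 4 residual degrees of freedom). Comparison D tested the slope of that ratio over the order egg, 1-cell, 16-cell and 128-cell (8 libraries, 2 residual degrees of freedom), and comparison E the slope in the unfractionated libraries of the same stages (4 libraries, 2 residual degrees of freedom). Slopes are log2 per stage step, which ignores the unequal times between stages. There is 1 library for each stage and fraction, so no fit holds replicates of a condition and every p-value measures the effect against the spread between stages only. Standard errors are the moderated ones of limma.

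Before the data were examined, 29 gene lists were fixed. They cover cytosolic ribosomal proteins, translation factors, proteasome subunits, the nuclear-encoded respiratory chain and ATP synthase, mitochondrially encoded mRNAs, histones, splicing factors, cell cycle and DNA replication, cytoplasmic polyadenylation and repression of maternal mRNA, deadenylation and mRNA decay, germ plasm, oocyte and egg genes, maternal transcription factors, first zygotic genes, enveloping layer, yolk syncytial layer, mesendoderm, ectoderm, chaperones, immediate early stress genes, signalling, chromatin and the cytoskeleton. Markers of ovarian follicle cells, blood, liver and skeletal muscle were included as cell types that could reach the samples from the mother. The 2 non-coding RNA lists held 3 tested members each, fewer than the minimum of 5, and were not tested. The other 27 lists, the RefSeq classes and the assembled loci make the 31 lists tested per comparison. Lists were tested with camera at a preset correlation of 0.01, with camera at a correlation estimated from the residuals, and with fry, each with Benjamini-Hochberg adjustment over the 31 lists. fry called 7, 20, 14, 0 and 0 lists in A to E, against 9, 20, 11, 7 and 2 by camera at the preset correlation. Numbers of list members past the threshold come from the adjustment over all genes, and the numbers in brackets marked as the list alone come from an adjustment within the list.

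The genes named follow a rule fixed before the data were examined. For each comparison and direction these are the 10 genes with the largest log2 value among those past the threshold with a mean of at least 5 counts per 1e6 (CPM) of the gene table and no overlap between the groups compared, up to 4 members of each list with the smallest p, and a set of genes printed whatever their result. Genes named only by clone or accession were counted but not named. Symbols were taken from the supplied gene-name table for 22547 genes and are printed as that table gives them. RefSeq classes for 18625 genes came from a RefSeq table of assembly GRCz12tu, used for names and classes and not for coordinates. Transcript boundaries, 3' UTR sequence and sequence motifs were not analysed here.

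In a simulation, 200 genes with a mean of at least 50 were changed by a known fold, with the designs and library factors of the real fits. Counts were drawn for each gene on its own, without correlation between genes. In B and E the simulated libraries had no other difference between stages. The simulated spread and fold sizes were set after earlier simulations had been seen, and recovery depends on them. In C, limma recovered 0%, 3% and 48.5% of genes changed 2-, 4- and 16-fold, and in A 4.5%, 52.2% and 95.5%. In B it recovered 0%, 26.9% and 98.5% of these. Per step changes of 1.5-, 2- and 4-fold were recovered at 11.9%, 50.7% and 65.2% in D and at 17.9%, 46.3% and 98.5% in E. The share of calls that were unchanged genes lay between 0% and 6.9% for limma, between 1% and 6.1% for edgeR and between 26.5% and 48.3% for DESeq2. DESeq2 counts are therefore given only as an alternative. In the real fits the residual is the spread between stages and genes vary together, so the shares there may differ and are not known.

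The software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.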

Results

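The series covers pooled wild-type zebrafish embryos at 6 stages: egg, 1-cell, 16-cell, 128-cell, 3.5 hpf and 5.3 hpf. At each stage the RNA was taken as a polysome-bound fraction, a polysome-unbound fraction and an unfractionated sample, with 1 library for each of the 18 combinations. Reads assigned to transcripts were 50.75 M to 66.05 M in the bound, 30.67 M to 71.65 M in the unbound and 35.78 M to 60.15 M in the unfractionated libraries. The 4 early unfractionated libraries were close to each other (Spearman rho 0.961 to 0.974 across 23195 genes). Bound and unbound libraries of the same early stage had a rho of 0.934 to 0.941, against 0.904 at 3.5 hpf and 0.955 at 5.3 hpf. No condition has replicates, so each p below measures an effect against the spread between stages.

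The bound and unbound fractions were compared to ask which mRNAs were enriched on polysomes across the 6 stages. mRNAs of the splicing machinery were the most polysome-rich group. Of 52 splicing factor mRNAs, 39 were higher in the bound fraction and the other 13 did not pass (44 higher for the list alone), with a median log2 ratio of 1.92 (0.44 with the 4 control entries). Scaling to these entries moved the median log2 ratio of all tested genes from −0.01 to −1.35, and library totals moved it to −0.54. List medians given below at those scales carry this shift and are not relative to all genes. SNRPD3 (ENSDARG00000013800.6), a core protein of the spliceosome, was 17.9-fold higher in the bound fraction (log2 4.16 ± 0.42 SE, 12 libraries). U2AF1, which recognises splice sites, was 7.27-fold higher (2.86 ± 0.25) and SF3A2, a spliceosome subunit, 7.14-fold (2.84 ± 0.23). Among the other genes with large ratios, the RNA-binding protein genes hnrnpr (ENSDARG00000014569.8) and ewsr1b were 13.6-fold (3.77 ± 0.31) and 12.1-fold (3.60 ± 0.34) higher, and the high mobility group genes HMGB2 (ENSDARG00000029722.6) and hmgb1b 14.5-fold (3.86 ± 0.37) and 12.6-fold (3.66 ± 0.41). Among genes with a symbol that met the naming rule, the largest ratio, srsf3a aside, was that of ctsla (ENSDARG00000007836.9), a cathepsin L protease, at 20.1-fold (4.33 ± 0.41). Its normalized counts were 124900 to 229597 in the bound and 5950 to 28954 in the unbound libraries. srsf3a, a splicing regulator, was listed at 0 in the unbound libraries of 5 stages, so no fold is given, and whether it shares reads with other loci was not tested.

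Some chromatin, cell cycle and mRNA decay factors were also higher in the bound fraction. Of 51 chromatin mRNAs, 22 were higher and 3 lower (24 and 5 for the list alone), with a median of 0.78 that became −0.70 when scaled to the 4 control entries. Of 57 cell cycle and DNA replication mRNAs, 16 were higher and 1 lower (21 and 3 for the list alone), with a median of 0.41 that became −0.16 with library totals and −1.06 with the control entries. The replication factors MCM7 (9.45-fold, 3.24 ± 0.25) and CDC6 (6.94-fold, 2.80 ± 0.39) and the mitotic cyclin CCNB1 (6.74-fold, 2.75 ± 0.49) were among them. Of the chromatin list, the cohesin subunits SMC3 (7.53-fold, 2.91 ± 0.31) and rad21a (7.33-fold, 2.87 ± 0.36) were higher. Of 49 deadenylation and decay mRNAs, 18 were higher and 4 lower (24 and 6 for the list alone; median 0.94, and −0.55 with the control entries), led by the RNA-binding protein KHSRP (4.67-fold, 2.22 ± 0.36), the exonuclease XRN1 (4.46-fold) and SMG5 of nonsense-mediated decay (3.47-fold, 1.80 ± 0.25). Of 22 histone mRNAs, 9 were higher and the other 13 did not pass (11 higher and 1 lower for the list alone; median 1.02, and −0.38 with the control entries). The maternal linker histone h1m was 6.31-fold higher (2.66 ± 0.51). Of 28 maternal transcription factor mRNAs, 9 were higher and 2 lower (12 and 2 for the list alone; median 0.68, and −0.70 with the control entries). Of 28 enveloping layer mRNAs, 6 were higher (7 for the list alone; median 0.75, and −0.60 with the control entries). ctnnb2 (ENSDARG00000023472.8), a beta-catenin of the maternal axis pathway, was 8.1-fold higher (3.02 ± 0.29). The calls for KHSRP, XRN1, SMG5 and h1m ended with the control entries, and that for ctnnb2 held. At the preset correlation, camera kept the calls for chromatin, cell cycle and histones in all 15 alternative settings. It lost those for decay and maternal transcription factors with the control entries, and that for the enveloping layer in 2 settings.

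mRNAs of ribosomal proteins lay on the other side. Of 83 cytosolic ribosomal protein mRNAs, 61 were lower in the bound fraction and the other 22 did not pass (70 lower for the list alone), with a median log2 ratio of −1.28 (−2.76 with the control entries). RPS12 (ENSDARG00000036875.6) was 5.17-fold lower (−2.37 ± 0.31) and rps27.1 4.45-fold lower. Of 13 mitochondrially encoded mRNAs, 6 were lower (10 for the list alone; median −1.25, and −2.73 with the control entries), led by the complex I subunits MT-ND1 (4.52-fold lower, −2.18 ± 0.46) and MT-ND2 (4.26-fold lower, −2.09 ± 0.42). Translation factors split, with 13 higher and 13 lower of 77 (15 and 18 for the list alone). EIF4A3, of the exon junction complex, was 6.03-fold higher (2.59 ± 0.27), while the elongation factor subunits eef1da (4.3-fold, −2.10 ± 0.21) and EEF1G (3.73-fold, −1.90 ± 0.26) were lower. Of 46 oocyte and egg genes, 5 were higher and 13 lower (8 and 17 for the list alone), without a call by camera. The oocyte homeobox gene LHX8 (5.44-fold, −2.44 ± 0.26), the growth factor bmp15 (5.12-fold, −2.36 ± 0.40) and buc, the organizer of the Balbiani body (3.81-fold, −1.93 ± 0.26), were lower. The glycolytic enzymes ENO3 (4.56-fold, −2.19 ± 0.27) and GAPDH (3.93-fold, −1.98 ± 0.29) were lower as well. The calls for bmp15 and buc ended without the stage block.

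**Figure D1:**
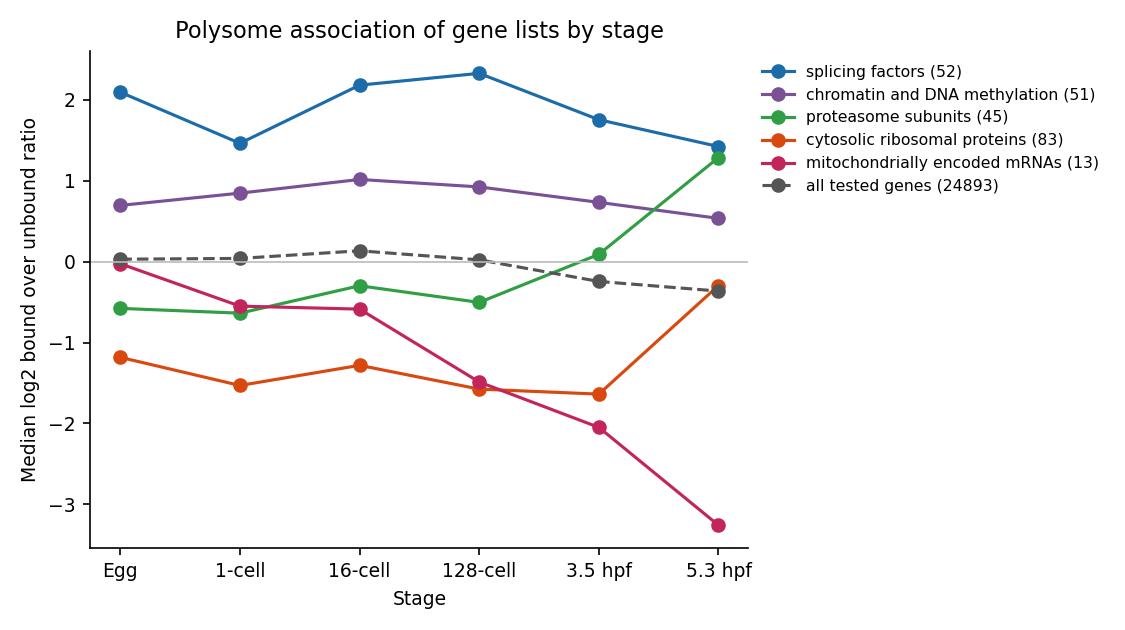
Median log2 ratio of polysome-bound over polysome-unbound normalized counts at each stage for 5 gene lists and for all 24893 tested genes. Each point is the median over list members in 1 bound and 1 unbound library.

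By limma with Benjamini-Hochberg adjustment, 2106 of 24893 genes were higher and 1768 lower in the bound fraction. edgeR on single transcripts gave 1358 and 391. camera called 9 of 31 lists, and none of the calls held with an estimated correlation. The adjusted p was 5.34e-29 for splicing factors and 1.07e-27 for ribosomal proteins (adjusted p = 0.142 and 0.367 with an estimated correlation). It was 2.18e-06 for chromatin, 0.00131 for cell cycle and 0.00131 for decay (adjusted p = 0.142, 0.272 and 0.785 with an estimated correlation). For mitochondrially encoded mRNAs and histones it was 7.26e-06 and 0.000433 (adjusted p = 0.761 and 0.785 with an estimated correlation). For the enveloping layer and maternal transcription factors it was 0.00134 and 0.00648 (adjusted p = 0.367 and 0.586 with an estimated correlation). The share of calls that were higher was 54.4% and depended on scaling, at 15.7% with library totals (1119 higher, 6028 lower), 77.3% with median centring (3252 and 954) and 1.3% with the 4 control entries (161 and 12589). The counts were 1132 and 699 without 16-cell and 1233 and 763 without 128-cell, and 1044 and 1086 were lower without egg and 1-cell.

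The late unfractionated libraries were compared with the 4 early ones to ask which mRNAs appeared or were lost around genome activation. Genes known to be transcribed first by the embryo made up the clearest group. Of 79 first zygotic genes, 64 were higher at 3.5 and 5.3 hpf and 1 lower (67 and 1 for the list alone), with a median log2 change of 5.88. Outside that list, starmaker, stm (ENSDARG00000035694.8), was 1970-fold higher (log2 10.95 ± 1.08, 6 libraries), with normalized counts of 16.6 to 194 at the early stages, 29748 at 3.5 hpf and 167526 at 5.3 hpf. The keratin krt18a.1 (ENSDARG00000018404.9) was 1310-fold higher (10.36 ± 1.37). tbx16 (ENSDARG00000007329.8), a T-box factor of the mesoderm, was 160-fold higher (7.32 ± 0.47) and went from 157 to 209 counts early to 16526 and 57368. The homeobox gene noto was 309-fold higher (8.27 ± 0.59), the ERK phosphatase DUSP6 337-fold (8.40 ± 0.57) and the mesoderm factor tbxta 91.4-fold (6.51 ± 1.23). FOXD3, a forkhead factor, was listed at 0 in all 4 early libraries and at 194 and 530 late.

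Members of tissue and signalling lists were higher too, although no list was called with an estimated correlation (adjusted p = 0.113 to 0.665 with an estimated correlation). Of 36 mesendoderm genes, 26 were higher and 1 lower (28 and 1 for the list alone; median 3.96). Of 27 enveloping layer genes, 17 were higher and 2 lower (19 and 2 for the list alone; median 5.38), among them grhl3, an epidermal transcription factor (243-fold, 7.92 ± 0.90), and klf17, a Krüppel-like factor (146-fold, 7.19 ± 0.76). Of 21 ectoderm and neural genes, 12 were higher and 1 lower (14 and 2 for the list alone; median 4.91), among them foxi1 (75.8-fold, 6.24 ± 0.65). Of 19 yolk syncytial layer genes, 11 were higher (14 higher and 1 lower for the list alone; median 2.96), among them the homeobox gene mxtx2 (477-fold, 8.90 ± 1.09) and the nuclear receptor HNF4A (76-fold, 6.25 ± 1.07). Of 37 signalling genes, 19 were higher and 2 lower (the same for the list alone; median 1.43), among them the ligand apela (161-fold, 7.33 ± 0.70). Its receptor gene aplnrb was 172-fold higher (7.42 ± 0.61). Of 18 immediate early stress genes, 10 were higher (11 for the list alone; median 1.31), among them the transcription factor JUN (85.6-fold, 6.42 ± 0.87). Of markers of tissues the early embryo does not have, 7 of 15 liver and yolk precursor genes (10 for the list alone; median 2.01) and 7 of 15 ovarian follicle genes (8 for the list alone; median 1.95) were higher. Blood genes (4 higher and 1 lower of 10, the same for the list alone) and muscle genes (3 higher of 12, 2 for the list alone) were not called by camera (adjusted p 0.338 and 0.532). Members of the liver list that were higher include the plasma protein genes hp (223-fold), tfa (40.8-fold) and FGB (3.94-fold) and the yolk precursor vtg1 (15.9-fold). Those of the follicle list include the receptor NOTCH3 (67.3-fold) and the steroid enzymes hsd17b1 (19.7-fold), CYP19A1 (17-fold) and hsd3b1 (14.6-fold).

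Of 45 oocyte and egg genes, 22 were lower and 3 higher at the late stages and 20 did not pass (27 and 5 for the list alone; median −1.15; camera adjusted p = 0.38 with an estimated correlation). The oogenesis-related gene org (ENSDARG00000076474.4) was 14-fold lower (−3.80 ± 0.33), with 13357 to 15153 counts early, 1599 at 3.5 hpf and 681 at 5.3 hpf. The meiotic kinase MOS (ENSDARG00000069744.5) was 12.2-fold lower (−3.61 ± 0.39), ZAR1L (ENSDARG00000055973.4), a regulator of maternal mRNA, 11.2-fold (−3.48 ± 0.50), BTG4, an adaptor of the deadenylase, 9.64-fold (−3.27 ± 0.70) and buc 7.12-fold (−2.83 ± 0.70). Of 20 germ plasm genes, 9 were lower and 1 higher (11 and 1 for the list alone; median −1.05), among them PIWIL2, a piRNA-binding protein (4.41-fold, −2.14 ± 0.28). The higher one of the oocyte list with the largest change was the chemokine cxcl12b (39.7-fold, 5.31 ± 0.61). Of 57 cell cycle genes, 19 were lower and 7 higher (the same for the list alone; median −0.58), with the anaphase inhibitor fbxo43 (6.72-fold, −2.75 ± 0.34) and the kinase CDK1 (3.27-fold, −1.71 ± 0.20) lower and the G1 cyclin CCND1 higher (120-fold, 6.91 ± 0.49). Of 94 nuclear-encoded respiratory chain and ATP synthase genes, 28 were lower and 2 higher (24 and 2 for the list alone; median −0.65), led by ATP5PD (5.23-fold, −2.39 ± 0.26). Of 31 genes for cytoplasmic polyadenylation and repression of maternal mRNA, 8 were lower and 2 higher (the same for the list alone; median −0.10), among them CPEB1 (3.05-fold, −1.61 ± 0.29).

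Splicing factors had 9 higher and 1 lower of 52 (1 higher for the list alone; median 0.62), and ribosomal proteins 7 higher of 83, none of which passed for the list alone (median 0.56, and −0.16 without 5.3 hpf). Proteasome subunits had 5 lower and 2 higher of 45 (3 and 1 for the list alone; median −0.15, and 0.10 without 3.5 hpf). Of 91 chaperone genes 8 were higher and 16 lower, of 51 chromatin genes 14 and 8, of 77 translation factors 6 and 9, of 49 decay genes 5 and 9, of 22 histones 3 and 3, of 28 maternal transcription factors 8 and 3, and of 30 cytoskeleton genes 2 and 6. The 13 mitochondrially encoded mRNAs did not pass. Among RefSeq classes, 29 of 70 lncRNA genes were higher and 4 lower (the same for the list alone; median 1.81), against 3360 higher and 2590 lower of 17311 protein-coding genes. Of 1062 assembled loci, 154 were higher and 105 lower (143 and 84 for the list alone; median −0.20, mean 0.35).

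**Figure D2:**
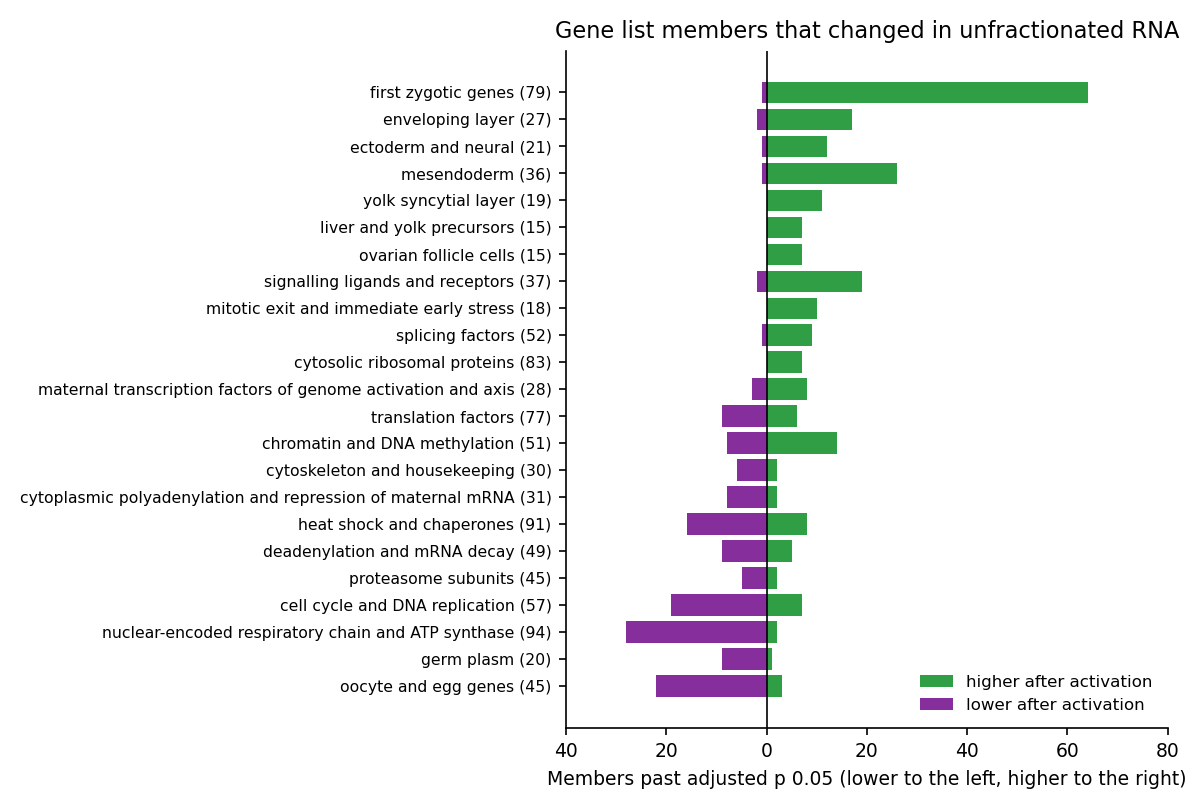
Numbers of list members higher or lower in the unfractionated libraries of 3.5 and 5.3 hpf than in the 4 early ones, by limma with adjusted p 0.05. Lists with at least 7 changed members are drawn.

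limma with Benjamini-Hochberg adjustment gave 5380 genes higher and 3120 lower of 23949, and edgeR on single transcripts 4846 and 1756. camera called 20 of 31 lists, none of them with an estimated correlation. The adjusted p was 2.69e-16 for first zygotic genes, 6.96e-07 for mesendoderm and 7.36e-05 for the enveloping layer (adjusted p = 0.322, 0.39 and 0.439 with an estimated correlation). It was 0.000638 for ectoderm, 0.000638 for stress genes, 0.00186 for signalling and 0.00554 for the yolk syncytial layer (adjusted p = 0.113, 0.121, 0.439 and 0.439 with an estimated correlation). Among the falling lists it was 1.09e-07 for the respiratory chain, 6.08e-07 for oocyte genes, 0.000582 for cell cycle and 0.000582 for germ plasm (adjusted p = 0.255, 0.38, 0.113 and 0.38 with an estimated correlation). For liver and follicle markers it was 0.0115 and 0.0397 (adjusted p = 0.255 for both with an estimated correlation). For splicing, ribosomal, proteasome and polyadenylation genes it was 0.00554, 0.0321, 0.0327 and 0.0494 (adjusted p = 0.681, 0.776, 0.611 and 0.255 with an estimated correlation). For lncRNA genes it was 0.001 (adjusted p = 0.113 with an estimated correlation). Over 12 alternative settings, camera kept the ribosomal call in only 6, the polyadenylation call in 8, the splicing call in 9 and the proteasome call in 10. Protein-coding genes ranked lower than the other genes although their median was 0.12 and their mean 0.48 (adjusted p 0.00329, and adjusted p = 0.113 with an estimated correlation), and so did assembled loci (0.0494, and adjusted p = 0.439 with an estimated correlation). The counts were 1556 and 1688 without 5.3 hpf and 4454 and 5039 without 3.5 hpf, and 1685, 1886, 1662 and 1975 were lower without egg, 1-cell, 16-cell and 128-cell. With median centring, 4087 were higher and 6569 lower, a share of 38.4% higher against 63.3%.

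The bound over unbound ratio was then compared between the 2 late and the 4 early stages, to ask which mRNAs gained or lost polysome association around genome activation. The median change of all tested genes was −0.51, and it was −0.24 with TMM scaling and 0.50 with the 4 control entries, so list medians are also given relative to it. List medians at another scale, against another reference or without a stage are given as they are, not relative to all genes. Proteasome subunits gained the most. Of 45 proteasome mRNAs, 17 had a higher ratio late and the other 28 did not pass (24 higher for the list alone). Their median change was 1.29, which is 1.80 above all genes. With the control entries their median was 2.42, where that of all genes was 0.50. The ratio of PSMD7 (ENSDARG00000102417.1), a lid subunit, changed 8.58-fold (log2 3.10 ± 0.48, 12 libraries), from −1.77, −1.77, −1.08 and −0.37 at the early stages to 2.23 and 1.48. The ratio of the base subunit PSMC1 rose 6.52-fold (2.71 ± 0.37). Of 77 translation factor mRNAs, 13 were higher and 1 lower (19 and 3 for the list alone; median 0.39, and 0.90 above all genes), among them the initiation factor subunit EIF3K (6.41-fold, 2.68 ± 0.34). Of 94 chaperone mRNAs, 12 were higher and 3 lower (15 and 3 for the list alone; median 0.10, 0.61 above all genes, and −0.11 against the unfractionated libraries), led by the chaperonin subunits CCT4 (ENSDARG00000013475.6; 6.07-fold) and CCT3 (5.7-fold, 2.51 ± 0.35). Of 83 ribosomal protein mRNAs, 7 were higher (11 higher and 1 lower for the list alone; median 0.25, 0.76 above all genes, and −0.48 without 5.3 hpf). Of 96 respiratory chain mRNAs, 7 were higher and 4 lower (10 and 5 for the list alone; median 0.11, mean −0.01, 0.62 above all genes, and −0.38 without 5.3 hpf).

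Other mRNAs lost polysome association. List medians with the control entries are given here as they are, where that of all tested genes was 0.50. The ratio of fbxo43 (ENSDARG00000104186.1), which holds the egg in meiosis, fell 70.3-fold (−6.14 ± 0.61), from 4.92, 4.10, 3.15 and 2.42 at the early stages to −2.43 and −2.55. CPEB1 (ENSDARG00000008454.9), which binds cytoplasmic polyadenylation elements, fell 12.5-fold (−3.64 ± 0.39) and the germ cell translation factor DAZL 11.9-fold (−3.57 ± 0.65). The B-type cyclins fell too, CCNB1 7.13-fold (−2.83 ± 0.43) and CCNB2 8.66-fold (−3.11 ± 0.46), as did the oocyte kinase WEE2 (7.86-fold, −2.97 ± 0.38). Of 49 decay mRNAs, 15 were lower and 2 higher (22 and 2 for the list alone; median −0.998, −0.49 relative to all genes, and 0.13 with the control entries). They include the deadenylase subunits CNOT7 (8.57-fold, −3.10 ± 0.37) and CNOT8 (6.13-fold, −2.62 ± 0.40). Of 46 oocyte mRNAs, 11 were lower (18 lower and 2 higher for the list alone; median −1.48, −0.97 relative to all genes, and −0.41 with the control entries). Of 22 histone mRNAs, 5 were lower, also for the list alone (median −0.97, −0.46 relative to all genes, and 0.16 with the control entries), among them the maternal histone h2af1al (19.2-fold, −4.26 ± 0.36) and h1m (6.81-fold, −2.77 ± 0.50). Over 13 alternative settings, camera lost the call for histones in 4, that for chaperones in 2 and that for decay in 1. Of 20 germ plasm mRNAs, 4 were lower (10 lower and 1 higher for the list alone; median −1.23, −0.72 relative to all genes, and −0.11 with the control entries); camera lost this call under TMM, library totals, median centring and the control entries and without 16-cell or 3.5 hpf. Of 13 mitochondrially encoded mRNAs, 6 were lower (12 for the list alone; median −2.08, −1.57 relative to all genes, and −0.95 with the control entries), among them MT-ND1 (5.7-fold, −2.51 ± 0.50). For these mRNAs the ratio gives only the fraction that held them. Where mitochondria lay in the fractions was not measured, so a loss of cytosolic polysomes is not claimed. Of 10 pseudogenes, 1 was lower (5 for the list alone; median −2.08). Splicing factors had 12 lower of 52, and cell cycle genes 5 higher and 12 lower of 57 (10 and 15 for the list alone), without a call by camera. Of 31 mRNAs for cytoplasmic polyadenylation and repression of maternal mRNA, 4 were higher and 4 lower (5 and 6 for the list alone), also without a call, with PUM3, a Pumilio-family RNA-binding protein, higher (9.62-fold, 3.27 ± 0.48) and CPEB1 and the helicase DDX6 (5.33-fold, −2.41 ± 0.39) lower. With the control entries the calls for CPEB1, DAZL, CCNB1, CCNB2, WEE2, CNOT7, CNOT8, DDX6, h2af1al, h1m and MT-ND1 ended and that for fbxo43 held. The values for shbg and AKAP6, the largest falls among genes with a symbol that met the naming rule, are treated as uncertain. Whether shbg and AKAP6 share reads with other transcripts was not tested.

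limma with Benjamini-Hochberg adjustment gave 587 genes with a higher and 1342 with a lower late ratio, of 24893. edgeR on single transcripts gave 91 and 37. camera called 11 of 31 lists, none of them with an estimated correlation. The adjusted p was 2.8e-14 for the proteasome, 1.28e-06 for translation factors, 3.59e-06 for ribosomal proteins, 0.00136 for chaperones and 0.00239 for the respiratory chain (adjusted p = 0.333, 0.236, 0.761, 0.333 and 0.778 with an estimated correlation). It was 6.8e-06 for mitochondrially encoded, 0.000206 for oocyte, 0.000629 for decay, 0.0133 for histone, 0.0388 for germ plasm and 0.0353 for pseudogene mRNAs (adjusted p = 0.566, 0.333, 0.333, 0.719, 0.476 and 0.42 with an estimated correlation). Every call rests on the 3.5 hpf libraries: without them limma left 0 higher and 0 lower (1418 and 2871 at unadjusted p 0.05), with a smallest adjusted p of 0.0529, although log2 changes such as those of PSMC1 (3.08) and CCT4 (2.87) stayed. The split of 30.4% higher became 51.9% with TMM (895 higher, 831 lower), 49.1% with library totals (859 and 891), 48.3% with median centring (826 and 884), 91.6% with the control entries (315 and 29) and 18.3% against the unfractionated libraries (160 and 716); the counts were 228 and 586 without egg, 313 and 744 without 1-cell, 170 and 449 without 16-cell and 224 and 626 without 5.3 hpf.

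Within the 4 stages before activation, the slope of the bound over unbound ratio was tested to ask which mRNAs moved on or off polysomes. Some cell cycle and oocyte mRNAs moved off. The ratio of BUB3 (ENSDARG00000075883.5), of the spindle checkpoint, fell 5.37-fold per stage step (log2 −2.43 ± 0.28, 8 libraries). Its bound counts were 7107, 5649, 649 and 427 from egg to 128-cell, and its unbound counts 363, 556, 1886 and 1928. BIRC5 (ENSDARG00000075621.4), of the chromosomal passenger complex, fell 4.43-fold per step (−2.15 ± 0.21) and its partner kinase AURKB 3.53-fold (−1.82 ± 0.20). The mitotic kinesin kif11 (3.31-fold, −1.73 ± 0.19) and the replication factor GINS2 (3.09-fold, −1.63 ± 0.17) fell as well. org fell 4.3-fold per step (−2.11 ± 0.20), from 71333 to 4524 bound counts and from 4111 to 15625 unbound. ZAR1L fell 4.44-fold (−2.15 ± 0.27) and MOS 2.29-fold (−1.20 ± 0.18). The control entries moved the median slope of all tested genes from −0.02 to 0.15, and list medians below at that scale carry this shift. Of 57 cell cycle mRNAs, 15 fell and 4 rose (16 and 5 for the list alone), with a median of −0.08 and a mean of −0.28 per step; the median was 0.09 with the control entries and 0.05 against the unfractionated libraries. Of 45 oocyte mRNAs, 8 fell (9 for the list alone; median −0.25, and −0.08 with the control entries). Of 91 respiratory chain mRNAs, 14 fell (16 for the list alone; median −0.20, and −0.03 with the control entries), led by ATP5PD (2.07-fold, −1.05 ± 0.16). Of 13 mitochondrially encoded mRNAs, 1 fell (5 for the list alone; median −0.39), which is not read as leaving cytosolic polysomes.

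Other mRNAs moved onto polysomes over the same stages. Of 22 histone mRNAs, 6 rose (10 rose and 1 fell for the list alone; median 0.39), among them h2ax, the histone variant of the DNA damage response (1.82-fold per step, 0.87 ± 0.16). Of 52 splicing factor mRNAs, 8 rose and 3 fell (the same for the list alone; median 0.14), led by SNRPB2 (1.92-fold, 0.94 ± 0.14). Of 28 maternal transcription factor mRNAs, 5 rose and 1 fell (6 and 2 for the list alone; median 0.16), among them foxh1, of the nodal pathway (1.51-fold, 0.60 ± 0.14). Over 12 alternative settings, camera lost the call for this list in 4, and its median went down to 0.025. hmgn1a (ENSDARG00000097102.2), a nucleosome-binding protein, rose 2.33-fold per step (1.22 ± 0.16), with bound counts of 19984, 22866, 73492 and 69047 and unbound counts of 49326, 41605, 29785 and 16862. C1D, an exosome cofactor, rose 2.28-fold per step (1.19 ± 0.13). LSM14B, which binds repressed maternal mRNAs, rose 1.73-fold (0.79 ± 0.12). Decay factors (2 rose and 7 fell of 49), genes for cytoplasmic polyadenylation (5 and 4 of 31), chromatin genes (5 and 5 of 51) and chaperones (7 and 5 of 91) had no call by camera. The calls for h2ax, SNRPB2, foxh1, hmgn1a and LSM14B ended with the control entries and without the 128-cell stage, and that for C1D held.

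**Figure D3:**
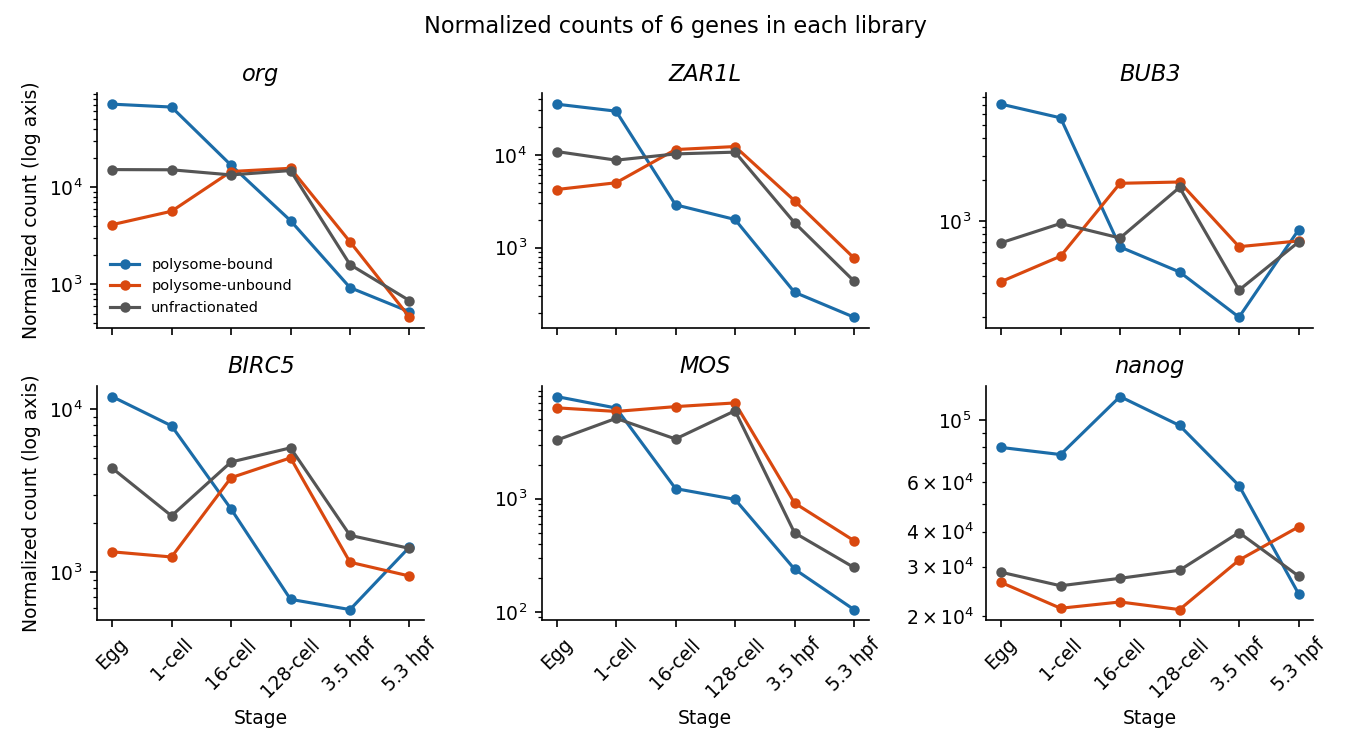
Normalized counts of 6 genes at each stage in the polysome-bound, polysome-unbound and unfractionated libraries, on a log axis. Each point is 1 library.

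By limma with Benjamini-Hochberg adjustment the ratio rose for 902 and fell for 1046 of 22250 genes. edgeR on single transcripts left 0 in each direction (2289 and 2194 at unadjusted p 0.05, smallest adjusted p 0.269), DESeq2 on transcripts gave 2586 and 2720, and edgeR on the joined genes 361 and 378, among them BIRC5, ZAR1L (−2.15) and MOS (−1.20) falling and C1D (1.18) rising. camera called 7 of 31 lists, none of them with an estimated correlation. The adjusted p was 6.68e-05 for mitochondrially encoded, 6.83e-05 for respiratory chain, 0.00465 for histone, 0.00465 for oocyte, 0.0162 for splicing, 0.0261 for cell cycle and 0.0285 for maternal transcription factor mRNAs (adjusted p = 0.906, 0.747, 0.906, 0.906, 0.906, 0.906 and 0.906 with an estimated correlation). Without the 128-cell stage 26 rose and 160 fell, and without 1-cell 1629 rose and 1637 fell; the control entries left 29 and 82, a share of 26.1% rising against 46.3%, and median centring gave 56.4% (1141 and 881).

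**Figure D4:**
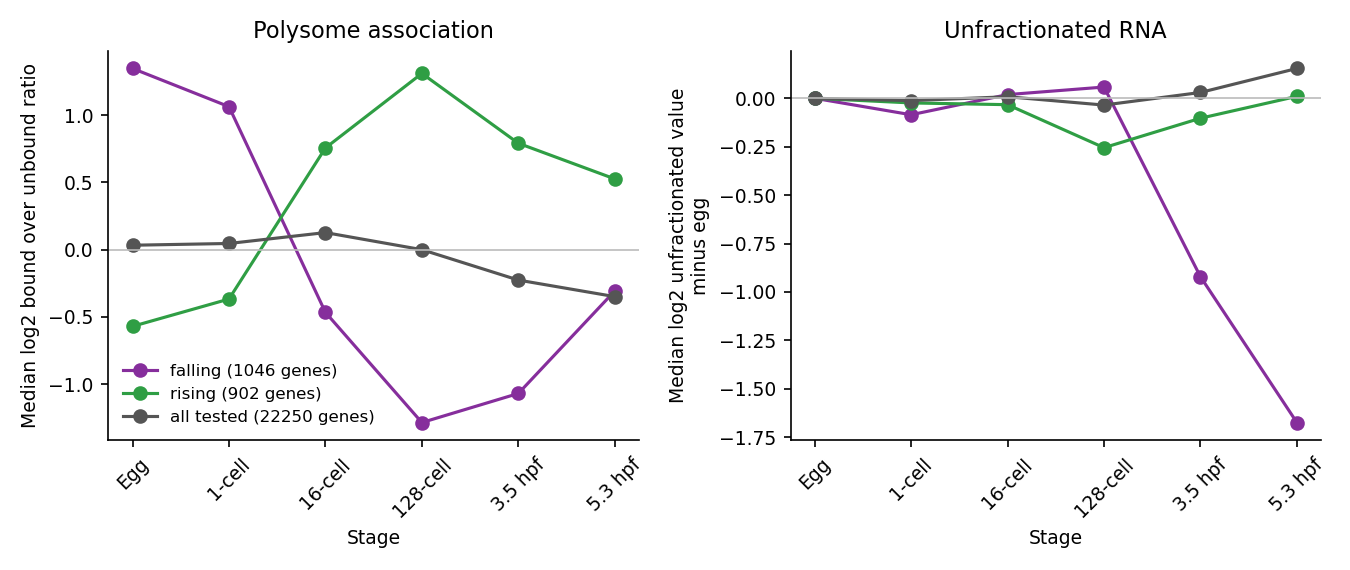
Median log2 ratio of bound over unbound, and median log2 unfractionated value relative to egg, at each stage for the 1046 falling, the 902 rising and all 22250 tested genes. Each point is a median over genes.

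The unfractionated libraries of the same 4 stages were tested for a slope, to ask whether total mRNA changed before activation. limma found 0 genes rising and 0 falling of 21173 after Benjamini-Hochberg adjustment (728 and 1001 at unadjusted p 0.05), with a smallest adjusted p of 0.605. edgeR on transcripts also left 0 and 0, and DESeq2 gave 259 and 273. The values of BUB3, org, ZAR1L and MOS in the unfractionated libraries did not pass, MOS having a slope of 0.20 ± 0.13. Slopes of other genes included those of rgs14a, a regulator of G-protein signalling (0.49 ± 0.10), the initiation factor EIF1B (−0.32 ± 0.06) and the cadherin cdh1 (−0.29 ± 0.06), none of which passed. Splicing factors had a median slope of −0.12 and first zygotic genes of 0.19 without a member that passed, with an adjusted p by camera of 2.07e-05 and 0.00427 (adjusted p = 0.789 for both with an estimated correlation). With the 16-cell and 128-cell libraries set against egg and 1-cell, 5 genes were higher and 2 lower by limma; the higher ones with a symbol are the transglutaminase TGM2 (6.05 ± 0.45) and the histone hist1h2a2 (3.65 ± 0.31), and the rest are named by clone or have no symbol.

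The calls for total mRNA and for the late change in ratio were crossed to ask whether mRNAs that rose or fell in total also changed their polysome association. Among 23823 genes tested in both, those lower in total at the late stages were over-represented on both sides, with 308 also lower in ratio against 174.3 expected (odds ratio 2.11, adjusted p 6.93e-25) and 137 higher in ratio against 76.9 expected (odds ratio 2.07, adjusted p 7.89e-12). CPEB1, DAZL and fbxo43 are among the former and PSMC1 among the latter. Genes higher in total were under-represented, with 18 higher in ratio against 131.2 expected (odds ratio 0.107, adjusted p 4.38e-41) and 102 lower against 297.5 (odds ratio 0.274, adjusted p 3.5e-48). Genes near the floor at the early stages can hardly be called for a change in ratio. Of 79 first zygotic genes, 0 were higher and 1 lower in ratio. This crossing was not repeated within bins of expression level. Neither the over-representation nor the depletion, each found in both directions, is therefore read as an effect on polysome association. The tests are two-sided Fisher's exact tests with Benjamini-Hochberg adjustment, and the libraries of the 2 comparisons do not overlap. They take genes as independent, although genes vary together, so their p-values do not measure variation between libraries.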

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

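The test of grouping for the bound against the unbound fraction was chosen only after the result was seen, and the other tests of grouping before. The difference between late and early stages in the bound over unbound ratio was flagged as a difference between groups by its interaction term, with 587 genes higher and 1342 lower. Only 15 groupings of the stages into 2 and 4 exist, too few for a share under 0.05, and the real one gave 1929 calls against at most 56 in another.

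The slope of the ratio from egg to 128-cell was flagged in the same way, with 902 genes rising and 1046 falling. Counting an order and its reverse once, only 12 orders of the 4 stages exist, again too few, and the real order gave 1948 calls against at most 1541, with egg and 1-cell swapped.

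For the bound against the unbound fraction, the fraction labels were swapped within stages in all 32 ways, so that each stage kept a library on each side. The real grouping gave 3874 calls and no other more than 3, so 1 of 32 was as large, the smallest share these swaps can give. A test chosen after the result was seen cannot exclude a chance assignment of the fractions. A drawing of 100 splits across stages, made before, had a highest other count of 56.

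Reads on the 4 control entries were flagged because they lie outside the main measurement. They took between 0.52% and 2.25% of reads in the fraction libraries, while the unfractionated libraries held 5 to 59 such reads. Over the 12 fraction libraries the shares of the entries among the 4 were 72.5% to 80.9%, 2% to 3%, 2.6% to 5.5% and 12.7% to 19.5%. Relative to all other reads, those on these entries were 1.98, 3.58, 2.51, 1.6 and 2.42 times as many in the bound as in the unbound library from egg to 3.5 hpf, and 0.75 times at 5.3 hpf, so the choice to scale to them moves the ratios. What the entries are and their amounts are not given in the sources used here, and a test for a mixture of fixed composition was dropped because its limit had been set after the shares were seen.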

How the results depend on the processing

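Of the other fits to the gene table, those with no filter on low values and a pseudocount of 10 kept each count of genes within 1.5 times of the main one. The values below are genes higher and lower in each comparison, A to E, wherever a count moved by more, and the cause was not tested. With TMM, C had 895 and 831. With library totals, A had 1119 and 6028, and C had 891 lower. With median centring, A had 3252 and 954, B had 6569 lower, and C had 884 lower. With the 4 control entries, A had 161 and 12589, C had 315 and 29, and D had 29 and 82. With the unfractionated libraries as the reference, C had 160 and 716. Without the stage block, A had 1440 and 395, a share of 78.5% higher. With all 18 libraries in the fit, A had 3511 and 3558 and B had 8759 and 5852. For B this fit had no term for stage, so the libraries of the same stage counted as independent. Its larger counts are not read as stronger evidence. With 16-cell and 128-cell against egg and 1-cell, E had 5 and 2.

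With edgeR on single transcripts and TMM, A had 1358 and 391, B had 1756 lower, C had 91 and 37, and D had 0 and 0. With DESeq2 size factors instead, A had 1109 and 445, B had 1885 lower, C had 98 and 105, and D had 0 and 0. Without a filter, A had 1297 and 325, B had 1413 lower, C had 71 and 24, and D had 0 and 0. With DESeq2 on transcripts, A had 4204 and 3210, B had 4978 lower, C had 1942 and 3122, D had 2586 and 2720, and E had 259 and 273. On the joined genes, of which fewer were tested, edgeR gave 778 and 479 in A, 2560 and 1110 in B, 251 and 211 in C and 361 and 378 in D, and limma gave 706 and 735, 2831 and 1310, 190 and 488, and 387 and 375.

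Leaving out 1 stage moved many counts, up or down. In A these were 1044 lower without egg, 1086 lower without 1-cell, 1132 and 699 without 16-cell, and 1233 and 763 without 128-cell, with at most 2546 and 1961 without 5.3 hpf. In B they were 1685 lower without egg, 1886 without 1-cell, 1662 without 16-cell, 1975 without 128-cell, 5039 without 3.5 hpf, and 1556 higher and 1688 lower without 5.3 hpf, with at most 4992 higher without 128-cell. In C they were 228 and 586 without egg, 313 and 744 without 1-cell, 170 and 449 without 16-cell, 0 and 0 without 3.5 hpf, and 224 and 626 without 5.3 hpf, with at most 654 and 1461 without 128-cell. In D they were 1629 and 1637 without 1-cell, and 26 and 160 without 128-cell.

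With the control entries as the scale, the log2 ratio in A turned negative for pou5f3 (−0.046), YBX1 (−0.521), ZAR1 (−1.147), klf17 (−1.276), sox19b (−1.377), patl1 (−0.272), eif4e1c (−0.452), HSPB1 (−0.083), DDX4 (−0.211), SP1 (−0.165) and notch2 (−0.412). Against the unfractionated libraries, erlin2 in C was −0.228 and ELK4 in D was −0.098. Among lists, and with single stages left out, the proteasome in B had medians from −0.513 without 5.3 hpf to 0.098 without 3.5 hpf (−0.656 with median centring). Ribosomal proteins ranged from −0.161 without 5.3 hpf to 1.232 without 3.5 hpf in B and from −0.481 to 1.105 in C with the same stages left out (1.376 with the control entries). The respiratory chain in C ranged from −0.383 to 0.681 in the same way (1.218 with the control entries).

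Of the values for named genes under an alternative, 7822 kept their direction and their side of the threshold and 657 lost a call. The genes named for B in the report kept their calls in all limma fits of the gene table, and those named for C lost theirs without 3.5 hpf. In D, BUB3, BIRC5, org, ZAR1L, AURKB, kif11 and GINS2 kept theirs in all limma fits of the gene table, while no transcript passed by edgeR. BUB3, org, AURKB and kif11 were not among the joined genes. Of the values for lists, 524 kept their call at the preset correlation and 45 lost it. Over the alternatives the adjusted p ranged from 0.00878 to 0.244 for polyadenylation genes in B and from 0.00547 to 0.47 for germ plasm in C. Each library had at least 30.67 M assigned reads. In the main fits, genes that did not reach 10 normalized counts in at least 2 libraries of the fit were not tested. A planned search for cytoplasmic polyadenylation elements was not run because no sequence of the 3' UTRs was used here.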

Other observations

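The tests of the overlap by expression level and of the 5.3 hpf libraries in this part were chosen only after the result was seen, as was the overlap itself. Of the maternal activators of the genome, pou5f3 was 2.7-fold higher in the bound fraction over all stages (1.44 ± 0.38 SE; limma, Benjamini-Hochberg adjusted p 0.0255), and nanog had 1.36 ± 0.44 (adjusted p 0.0587). Without any 1 of the early stages, with library totals or with the control entries, pou5f3 did not pass. The log2 ratio of nanog was 1.60, 1.82, 2.44 and 2.18 from egg to 128-cell, 0.88 at 3.5 hpf and −0.79 at 5.3 hpf. That of sox19b was 0.42, 0.02, 1.61 and 1.43 early, then −1.31 and −1.54, a late change of −2.29 ± 0.51 (adjusted p 0.0264) that did not pass with the control entries or without 3.5 hpf. The late changes of pou5f3 (−1.61 ± 0.46, adjusted p 0.0639) and nanog (−1.96 ± 0.58, adjusted p 0.0691) did not pass.

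Mitochondrially encoded mRNAs had a median log2 ratio of bound over unbound of −0.03, −0.55, −0.59, −1.49, −2.05 and −3.26 from egg to 5.3 hpf. For MT-ND1, of complex I, the ratio was −0.94 in the egg and −4.34 at 5.3 hpf. All genes with a symbol that begins with mt-, a wider rule than that of the list, made up 0.31% to 0.737% of the bound and 1.199% to 3.547% of the unbound gene table. Nuclear-encoded respiratory chain mRNAs had medians of 0.04, −0.14, −0.44, −0.90, −0.44 and 0.61 at the same stages.

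A hypothesis was that mRNAs leaving polysomes before genome activation are those cleared after it. Of the 1046 genes whose ratio fell from egg to 128-cell, 706 were lower in the unfractionated libraries of 3.5 and 5.3 hpf, against 148.7 expected (67.5%; Fisher's exact odds ratio 15.9, 95% interval 13.9 to 18.3). The 2 sets of calls share no library. Fisher's test takes genes as independent, but genes vary together and each condition has 1 library. The interval, and the limits used below, therefore do not measure variation between libraries and may be too narrow. The median log2 ratio of the falling genes was 1.35, 1.06, −0.47 and −1.29 from egg to 128-cell, while their unfractionated values relative to egg were 0, −0.09, 0.02 and 0.06 at these stages, −0.92 at 3.5 hpf and −1.67 at 5.3 hpf. Of the 902 rising genes, 72 were lower late against 128.2 expected (odds ratio 0.512) and 63 higher against 162.2 (odds ratio 0.332). Of the falling genes, 10 were higher late against 188.1 expected (odds ratio 0.0416). Genes near the floor before activation can hardly pass the slope test in either direction. These 3 overlaps were not tested within bins of expression level, and no effect is read from them.

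The overlap held within each of the upper 3 of 5 equal bins of mean unfractionated value, where the lowest limit of the odds ratio was 5.13. The bin value was the mean over all unfractionated libraries, including the late ones that decide which genes were lower after activation. The overlap was thus present at each of these mean levels, but the bins cannot separate it from level before activation. Level within a bin was not held constant, so a dependence on level was not excluded. The lower 2 bins hold only 24 falling genes and, at a limit of 1.51, could not tell; a single test over all bins, written down before it was run, was not met there and was divided in this way after the result was seen. Splitting of reads between transcripts predicted no overlap among joined genes, where the lower limit was 13.9. Scaling of the fraction libraries predicted loss of the overlap under another scale, where the lowest odds ratio was 15.4. A new scale shifts all genes of a library alike. Of the falling calls, 1044 of 1071 with TMM and 79 of 82 with the control entries were also main calls. The odds ratio could therefore hardly drop, and the test of scaling cannot decide. The last 2 tests were written down before they were run. The unfractionated libraries were not rescaled. Many genes whose ratio fell before activation were lower in total RNA after it, which leaves room for loss of polysome association preceding clearance. The order in single genes was not tested.

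At 5.3 hpf the bound and unbound libraries were the most alike of any stage, with a rho of 0.955, and the median ratio of ribosomal protein mRNAs was −0.30 against −1.18 to −1.64 at the other stages. Mixing of the fractions would bring every group towards an even ratio, but the mitochondrially encoded mRNAs lay at −3.26, farther from even than at any other stage. This argues against complete mixing of the 2 fractions. Partial mixing cannot be told from these mRNAs, whose ratio was already moving away from even, from −0.03 in the egg to −2.05 at 3.5 hpf. Scaling of these libraries would leave the ribosomal protein mRNAs as far from all genes as before, but they lay 0.068 above the median of all genes, against −1.21 to −1.60 at the 5 other stages. With 1 library per fraction, a difference of gradient or collection at this stage was not tested.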
